A study of Mus musculus with 6 samples.

How the data were processed

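RNA was sequenced on an Illumina HiSeq from 6 libraries of mouse embryos at embryonic day 14.5, per the labels. The 3 mechanoreceptor libraries (replicates 2, 8 and 9) came from dorsal root ganglia of embryos carrying the Ret-CreERT2 and Rosa26-Tdtomato alleles. Pregnant mothers had received 1.5 or 2 mg of 4-hydroxytamoxifen by gavage, per the labels' protocols, and the dose behind each library was not stated. The ganglia were dissociated with trypsin and the labelled cells were collected by fluorescence-activated sorting. The 3 midline libraries (replicates 2, 3 and 5) came from wild-type spinal cords that were frozen, stained with hematoxylin and cut by laser capture microdissection. The cells are described in the labels as dorsal column midline cells derived from the roof plate. Cell type therefore coincided with tissue, isolation method, genotype and tamoxifen, and no term could separate them. The labels did not say whether the replicates came from separate embryos or litters, or how many embryos entered a library. The p-values therefore measure only the spread between these samples, which may be technical in part.

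The authors deposited a table of whole-number read counts per RefSeq transcript and sample, with the mouse build mm9 and edgeR named in the submitters' processing notes, without a version. The aligner and the counting tool were not given in the sources used here. The table held 28644 transcript rows for 22869 gene symbols, of which 3705 had more than 1 row. A read in an exon shared by several transcripts can stand in each of their rows, so sums over rows exceed the reads sequenced. The same deposited table held log2 expression values whose largest values were equal in all 6 samples, as quantile normalization gives. It also held the authors' log2 fold change and false discovery rate p-value of each row. In all 28644 rows the authors' marks of a difference matched a false discovery rate under 0.05 with a fold of at least 2. A further deposited table listed pathway enrichments of the genes higher in the midline, with a gene number, a fold enrichment ratio and a Benjamini-adjusted p-value per pathway. The layout of that table is that of a KEGG pathway search, per the file headers, and its background was not described.

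For each gene symbol the transcript row with the highest total count over the 6 samples was kept. Total counts over transcript rows were 13801474, 13291511 and 12031898 in mechanoreceptor libraries 2, 8 and 9, and 8081153, 5599811 and 7971480 in midline libraries 2, 3 and 5. Over the kept rows they were 9879250, 9567100 and 8670717, and 5643044, 3963051 and 5648607. At these depths 3 counts, taken as the floor of a library, were worth 0.346 to 0.669 CPM (counts scaled by library size, as the cpm function of edgeR gives). Strand was not stated in the sources used here, so overlapping and antisense genes could not be told apart. Of 14068 genes with at least 100 counts, 12 had the same 6 counts as another symbol, and such paralogs are reported as shared. Gene names are those of the table, with the current name added at least once where the RefSeq annotation of GRCm38.p6 gives another for the transcript of a gene the rule took. No positions are given, since the annotation at hand is of another build.

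Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15314, and library sizes were scaled by the TMM method. The quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest) compared the 3 mechanoreceptor with the 3 midline libraries on 4 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes tested, and genes with an adjusted p under 0.05 are called different. Every adjusted p-value of a gene is from this test unless another is named. The log2 fold change is mechanoreceptor minus midline, so a negative value means higher in the midline. Its standard error (SE) is the absolute log2 fold change divided by the square root of F. CPM values are scaled by TMM and given as mean ± SD over n = 3 libraries. Where a group had 0 counts in all libraries, the fold is a lower bound against 3 counts over the whole group. Where it had 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval. Shares of counts carry Wilson 95% intervals. Intervals and floors cover counting error only.

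The rule for the genes named was fixed before the data were examined. It took Ret in every sample first. It then turned to called genes with non-overlapping groups and a mean of at least 50 CPM in the higher group. Of these it took the 12 with the largest fitted fold in each direction, also where a group had 0 counts. Chance alone makes groups of 3 libraries non-overlapping in 10% of genes. From each of 26 lists of cell type markers and gene functions, also fixed then, it took up to 4 called members in the majority direction, up to 2 in the other, and up to 2 not called, by mean CPM. Some genes the rule took are not reported here, and none was put in their place. A further 13 genes are named outside the rule and were chosen after their values were seen: Rfx2, Plxna3, Unc5b, Bdnf, Fgf1, Cntn3, Dscaml1, 2610307P16Rik, Lmx1a, Msx1, Sox2, Maf and Fos. The 3 lists of skeletal muscle, keratinocyte and cartilage genes were written after the largest changes had been seen. Each fixed list was tested with camera in limma 3.58.1 on the edgeR fit, with a preset correlation of 0.01 between genes and adjustment over the 26 lists. An estimated correlation was the alternative. Members past the threshold are counted over all genes tested and, beside that, adjusted over the list alone.

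The same functions were tested on simulated data in 10 draws, made from the means, library sizes and dispersions of the real samples. In each draw 200 genes were changed, and a separate list of 25 genes was raised 2-fold in mechanoreceptors. Each draw had 14835 to 14885 genes tested. The quasi-likelihood test recovered 506 of 980 genes changed 4-fold (51.6%) and 19 of 972 changed 2-fold (1.95%), with median estimated folds of 4.06 and 1.99. Of its 579 calls, 50 (8.64%) were unchanged genes, which is above the 5% aimed at. DESeq2 recovered 72.6% and 17.9%, with 390 of 1337 calls (29.2%) on unchanged genes. In limma-voom 46.0% and 1.75% were recovered, with 7.81% of calls unchanged. Far more genes were called in the real samples, which eases the adjusted threshold, so these shares hold for the simulated setting only. The changed list of 25 genes was called by camera in 10 of 10 draws and 0 of 200 unchanged lists were called, with either correlation. Simulated genes were drawn independently, while members of a real list can move together. The estimated correlation was 0.82 in the proliferation list. These draws therefore do not show how the preset correlation performs on the real lists.

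Alternatives set before the data were examined were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter or a stricter one (at least 10 counts in 3 samples and a mean of 5 CPM), glmTreat against a 2-fold change, an adjusted p under 0.01, omission of the haemoglobin genes, omission of each library in turn, fry in place of camera, and lists without shared genes. Added after the data were seen were the rows the authors marked as best, all transcript rows, limma on the deposited log2 values, and omission of the muscle, keratinocyte and cartilage genes. No mitochondrial-genome genes were in the table. Plots were drawn with matplotlib 3.10.9.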

Results

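The series compared RNA from Ret-positive RA mechanoreceptors of the dorsal root ganglia, the sensory ganglia beside the spinal cord, with RNA from cells of the dorsal column midline, all from mouse embryos at stage E14.5. Mechanoreceptors send central axons into the dorsal columns of the spinal cord. The midline cells lie between the left and right columns and derive from the roof plate, the dorsal midline of the embryonic cord. Each group held 3 libraries, with total counts of 12031898 to 13801474 in mechanoreceptors and 5599811 to 8081153 in the midline. The comparison asked which transcripts differed between both cell types, including those through which axons and midline cells could meet.

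Ret, which encodes the receptor kinase by which the sensory cells were labelled, was far higher in every mechanoreceptor library (988, 1036 and 788 CPM) than in midline libraries 2, 3 and 5 (13.6, 41.9 and 20.8 CPM, log2 fold change 5.21, SE 0.45, adjusted p = 0.000361). Among the largest differences toward mechanoreceptors, P2rx3, an ATP-gated ion channel, stood at 890.1 ± 202 CPM in mechanoreceptors and 3.62 ± 2.29 CPM in midline libraries (SD, n = 3; log2 fold change 7.91, SE 0.50, adjusted p = 0.000155), and Prph, the intermediate filament peripherin, at 2954 ± 894 against 20.1 ± 16.4 CPM (log2 fold change 7.19, SE 0.73, adjusted p = 0.000605). The sodium channel gene Scn7a (7.06, SE 0.58), the synuclein gene Sncg (6.72, SE 0.38), the actin regulator Avil (6.57, SE 0.28) and the transcription factor genes Isl2 (8.003, SE 0.64) and Pou4f2 (6.45, SE 0.30) were among the 12 largest, with Ppp1r1c, Cpne6, Gm16551, Tusc5 (now Trarg1) and Pirt, all with log2 fold changes from 6.45 to 8.003.

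Toward the midline, the 3 genes with the largest fitted folds had 0 counts in all mechanoreceptor libraries. Their rank rests on fitted values, and their lower bounds do not place them above all others, as the ratio of Krt5 was larger. Lamp5, listed as 6330527O06Rik, was at least 898-fold higher in the midline, Mlc1, an astrocyte membrane protein gene, at least 679-fold, and Wnt1, a signalling ligand of the roof plate, at least 592-fold. Each bound moved most with its highest midline library left out, to 381-fold for Lamp5 without midline 3, and to 359.7-fold for Mlc1 and 269-fold for Wnt1 without midline 5. Without 1 of the mechanoreceptor libraries, where the floor is higher, the bounds lay from 577 to 608, 437 to 460.3 and 381 to 401. Their midline levels were 108 ± 109.998, 81.8 ± 66.8 and 71.3 ± 66.6 CPM (SD, n = 3). Gdf10, a ligand of the BMP family, reached 258 ± 229 against 0.282 ± 0.181 CPM (log2 fold change -9.76, SE 0.97, adjusted p = 0.000551). The other 8 of the 12 were the keratin gene Krt5 and 7 genes of the muscle contractile apparatus, Myh3, Myh8, Actc1, Mylpf, Tnnt2, Tnnt3 and Tnni2. In these 8 genes midline library 2 lay above both other midline libraries, as for Myh3 at 4302, 26.5 and 478 CPM in libraries 2, 3 and 5 and Krt5 at 205, 2.45 and 2.37 CPM. Without midline 2 the log2 fold change of Myh3 was -7.28 against -9.97 with it, and that of Myh8, Actc1, Mylpf, Tnnt2 and Tnnt3 lay from -7.29 to -6.81. The ratio of Tnni2 was then 101-fold against 751-fold, 95% interval 257 to 3641, and that of Krt5 59.0-fold against 1740-fold, 95% interval 312 to 68727. Krt5 lost its call without mechanoreceptor 2, mechanoreceptor 8 or mechanoreceptor 9 (adjusted p = 0.0651 to 0.0771). All 8 lost their calls with limma-voom, with adjusted p from 0.0665 to 0.217.

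Of 15314 genes tested, 5788 (37.8%) differed, 2886 of them higher in mechanoreceptors and 2902 higher in the midline. At least 2-fold differences were found in 4654, of which 2097 were higher in mechanoreceptors and 2557 in the midline. The median log2 fold change of the genes called was 1.38 toward mechanoreceptors and -2.31 toward the midline. Among the genes higher in the midline, 170 stood at least 4 times higher in midline library 2 than in both other midline libraries, against 9 for library 3 and 24 for library 5. Without midline library 2 the counts were 5325, 2873 and 2452. Without mechanoreceptor library 8 they fell to 3755, 1893 and 1862, and without mechanoreceptor library 2 the midline count was 1922. Upper-quartile scaling moved the share of calls that were higher in mechanoreceptors from 49.9% to 36.9%. The common biological coefficient of variation was 0.268 within mechanoreceptors and 0.422 within the midline, and the first principal component, with 72.5% of the variance, separated the groups. The second, with 11.1%, set midline library 2 (66.1) apart from midline library 3 (-63.0).

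**Figure D1:**
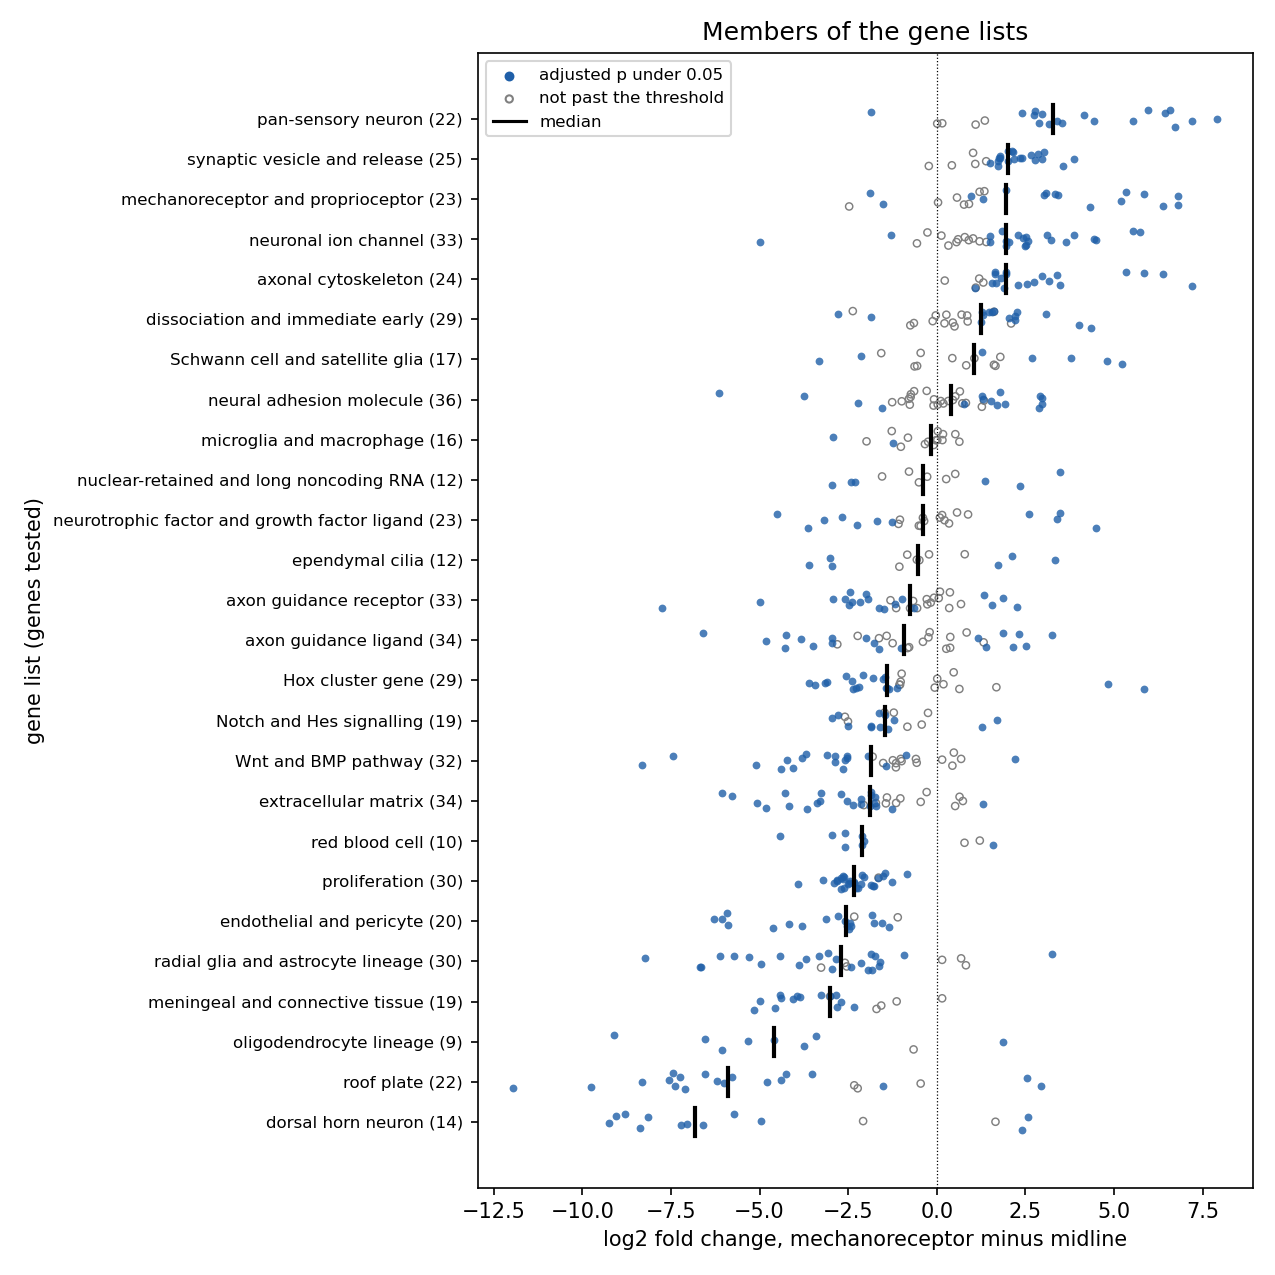
Log2 fold change (mechanoreceptor minus midline, horizontal axis) of each tested member of the 26 fixed gene lists (rows, number of genes tested in brackets), with filled points for an adjusted p under 0.05, open points otherwise and a bar at the median. Points are spread vertically for legibility, and points of genes with 0 counts in a group are fitted values and not bounds. The medians run from -6.82 in the dorsal horn neuron list to 3.27 in the pan-sensory neuron list.

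Marker genes of sensory neurons were higher in the sorted cells. Of 22 pan-sensory genes tested, 17 were higher in mechanoreceptors and 1 in the midline (17 and 1 adjusted over the list alone). The pan-sensory neuron list had camera adjusted p = 1.25e-18, and adjusted p = 0.0633 with an estimated correlation. Stmn2, a microtubule regulator of growing axons, stood at 3741 ± 456 against 479 ± 360.4 CPM and Tubb3, neuronal tubulin, at 1622 ± 148 against 156 ± 96.3 CPM (adjusted p = 0.003999 and 0.00167). The exception was Eya2, a transcriptional cofactor (log2 fold change -1.85, SE 0.53, adjusted p = 0.02599), which lost its call without mechanoreceptor 2, mechanoreceptor 8, midline 2 or midline 5 (adjusted p = 0.0546 to 0.0857) and on the deposited log2 values (adjusted p = 0.096).

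In the mechanoreceptor and proprioceptor list 14 of 23 genes were higher in mechanoreceptors and 2 in the midline (17 and 2 adjusted over the list alone). The mechanoreceptor and proprioceptor list had camera adjusted p = 1.07e-10, and adjusted p = 0.0733 with an estimated correlation. The neurofilament genes Nefm (7197 ± 2111 against 126 ± 11.05 CPM, log2 fold change 5.84, SE 0.36, adjusted p = 0.000155) and Nefl (4466 ± 1301 against 111 ± 55.1 CPM, 5.33, SE 0.48), the GDNF family receptor gene Gfra2 (3.41, SE 0.57) and the transcription factor gene Maf (128 ± 1.22 against 52.2 ± 21.3 CPM, 1.30, SE 0.30) were among them. Ntrk2, the receptor of brain-derived neurotrophic factor, was higher in the midline (361 ± 154 against 97.1 ± 17.9 CPM, log2 fold change -1.90, SE 0.33, adjusted p = 0.00397). Cntnap2 did not pass the test (log2 fold change 1.34, SE 0.50, adjusted p = 0.0682) except without midline 3 (adjusted p = 0.00372), with DESeq2 (0.0291), with limma-voom (0.0243) and with no count filter (0.0415). Gprasp1 (0.57, SE 0.23, adjusted p = 0.08903) passed without midline 3 (adjusted p = 0.0135) and with limma-voom (0.0497).

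Genes of the roof plate were higher in the midline libraries, with 17 of 22 tested members against 2 higher in mechanoreceptors (17 and 2 adjusted over the list alone). The roof plate list had camera adjusted p = 1.27e-09, and adjusted p = 0.137 with an estimated correlation. The zinc finger genes Zic1 (317 ± 179 against 2.27 ± 2.23 CPM, log2 fold change -7.10, SE 0.83, adjusted p = 0.000971) and Zic4 (-7.56, SE 0.90) and the homeobox genes Lmx1a (36.9 ± 33.5 against 0.207 ± 0.193 CPM, -7.39, SE 0.98) and Msx1 (69.4 ± 68.99 against 0.201 ± 0.246 CPM, -8.31, SE 1.09) were among them. The summed level of the list differed between midline libraries, at 662, 1423 and 2399 CPM in libraries 2, 3 and 5. The R-spondin gene Rspo2 (15.4 ± 2.08 against 2.62 ± 2.06 CPM, adjusted p = 0.0101) and the transthyretin gene Ttr (5.33 ± 1.46 against 0.711 ± 0.549 CPM, adjusted p = 0.0112) were the 2 members higher in mechanoreceptors. The stricter filter left 1 such member. Bmp7 did not pass the test (log2 fold change -2.23, SE 0.98, adjusted p = 0.108, or -1.26 without midline 2) except without mechanoreceptor 2 (adjusted p = 0.0395) and with DESeq2 (0.0403). Ednrb did not pass either (log2 fold change -0.46, SE 0.46, adjusted p = 0.463).

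The radial glia and astrocyte list moved the same way, with 23 of 30 genes higher in the midline and 1 in mechanoreceptors (26 and 1 adjusted over the list alone). The radial glia and astrocyte lineage list had camera adjusted p = 2.28e-10, and adjusted p = 0.112 with an estimated correlation. Nes, the neural progenitor filament nestin, stood at 899 ± 395 against 16.9 ± 5.31 CPM (log2 fold change -5.73, SE 0.47, adjusted p = 0.000314), Fabp7, a fatty acid binding protein of radial glia, at 2279 ± 1341 against 229.8 ± 86.5 CPM (log2 fold change -3.31, SE 0.56, adjusted p = 0.00366), and the progenitor transcription factor gene Sox2 at 40.7 ± 30.8 against 2.73 ± 1.401 CPM (-3.90, SE 0.70). Vim (-1.82, SE 0.32) and Dbi (-3.68, SE 0.58) were higher as well. The metallothionein gene Mt3 was the member higher in mechanoreceptors (3.99 ± 2.85 against 0.393 ± 0.147 CPM, adjusted p = 0.0136). The stricter filter removed it. Id4 (log2 fold change 0.69, SE 0.47, adjusted p = 0.275) and Apoe (log2 fold change 0.82, SE 0.37, adjusted p = 0.116) did not pass.

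**Figure D2:**
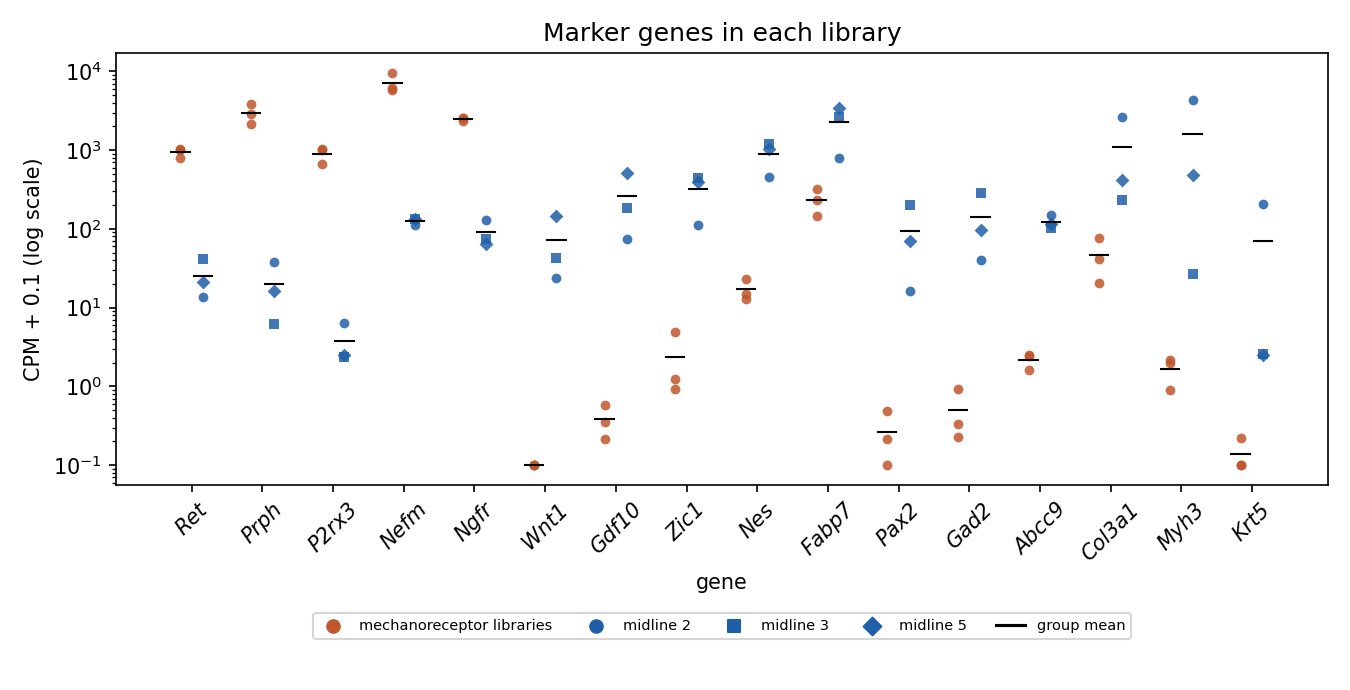
CPM plus 0.1 on a log axis for 16 genes in each library, with orange points for mechanoreceptor libraries, blue points for midline libraries 2, 3 and 5 (circle, square, diamond) and bars at group means. Ret, Prph, P2rx3, Nefm and Ngfr lie higher in all mechanoreceptor libraries, the other 11 higher in all midline libraries, and midline library 2 lies highest for Myh3 and Krt5.

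Dorsal horn neuron genes were also higher in the midline libraries, with 10 of 14 tested members against 2 higher in mechanoreceptors (11 and 2 adjusted over the list alone). The dorsal horn neuron list had camera adjusted p = 0.0006899, and adjusted p = 0.2896 with an estimated correlation. Their median log2 fold change was -6.82, or -6.11 with genes at 0 counts set to their bound. The transcription factor genes Pax2 (94.9 ± 93.6 against 0.166 ± 0.197 CPM, log2 fold change -9.05, SE 1.23, adjusted p = 0.001599) and Tfap2b (-6.60, SE 1.14) and the GABA synthesis genes Gad1 (-5.73, SE 1.03) and Gad2 (-8.38, SE 0.97) were highest in midline library 3, as for Pax2 at 16.04, 198 and 70.2 CPM in libraries 2, 3 and 5. The summed level of the list was 472, 1419 and 586 CPM in these libraries. Zfhx3 (log2 fold change 2.58, SE 0.32, adjusted p = 0.00118) and the glutamate transporter gene Slc17a6 (log2 fold change 2.41, SE 0.60, adjusted p = 0.0165) were higher in mechanoreceptors, and Slc17a6 lost its call without mechanoreceptor 2 or mechanoreceptor 8 (adjusted p = 0.0509 to 0.0517). The count toward mechanoreceptors was then 1. Foxd3 (1.66, SE 0.74, adjusted p = 0.112) passed only on the deposited log2 values (0.0208).

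Of 9 oligodendrocyte lineage genes, 7 were higher in the midline and 1 in mechanoreceptors (7 and 1 adjusted over the list alone), and without mechanoreceptor library 2 the midline count was 4. The oligodendrocyte lineage list had camera adjusted p = 0.0004795, and adjusted p = 0.118 with an estimated correlation. The growth factor receptor gene Pdgfra (115 ± 80.1 against 8.59 ± 5.04 CPM, log2 fold change -3.73, SE 0.63, adjusted p = 0.00362), the proteoglycan gene Cspg4 (-6.07, SE 0.86) and Gpr17 (-5.32, SE 0.70) were among the 7. Cspg4 also stood in the endothelial and pericyte list. In midline libraries 2, 3 and 5 Pdgfra stood at 206, 78.5 and 58.7 CPM and Cspg4 at 54.7, 23.9 and 28.6 CPM, both highest in library 2. Gpr17 was highest in library 3 (10.3, 17.0 and 8.37 CPM). Sox8 (-3.42, SE 0.95) lost its call without mechanoreceptor 2, mechanoreceptor 8 or midline 2 (adjusted p = 0.06301 to 0.0927), and Mog did not pass (-0.66, SE 0.66, adjusted p = 0.462). Mbp, which encodes myelin basic protein, was higher in mechanoreceptors (16.3 ± 5.69 against 4.49 ± 1.72 CPM, log2 fold change 1.87, SE 0.45, adjusted p = 0.0135). It lost its call without mechanoreceptor 8 (adjusted p = 0.0534), where the mechanoreceptor count was 0, and the transcript row marked best by the authors gave -0.95 (adjusted p = 0.186). In the Schwann cell and satellite glia list 5 of 17 genes were higher in mechanoreceptors and 2 in the midline (5 and 2 adjusted over the list alone). The Schwann cell and satellite glia list had camera adjusted p = 0.0174, and adjusted p = 0.449 with an estimated correlation. The neurotrophin receptor gene Ngfr (2492 ± 135 against 90.01 ± 35.8 CPM, log2 fold change 4.79, SE 0.36, adjusted p = 0.000232), which neurons also express, S100b (5.24, SE 0.48) and Gfra3 (3.79, SE 0.59) were among the 5. That list's count toward mechanoreceptors was 3 without mechanoreceptor library 2, midline library 3 or midline library 5, and 9 on the deposited log2 values. Fabp7 and Moxd1 were higher in the midline, and Moxd1 (-2.15, SE 0.62, or -1.31 without midline 2) lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 2 (adjusted p = 0.07705 to 0.125), with limma-voom (0.0534) and on the deposited log2 values (0.224). The midline count was then 1.

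Vascular genes were higher in the midline libraries, with 18 of 20 members in that direction and 0 in the other (18 and 0 adjusted over the list alone). The endothelial and pericyte list had camera adjusted p = 2.36e-13, and adjusted p = 0.112 with an estimated correlation. The pericyte channel subunit gene Abcc9 (123 ± 23.9 against 2.06 ± 0.485 CPM, log2 fold change -5.89, SE 0.30, adjusted p = 8.02e-05) and the endothelial receptor gene Kdr (116 ± 9.42 against 16.8 ± 11.99 CPM, log2 fold change -2.79, SE 0.49, adjusted p = 0.00411) were among them, at summed list levels of 947, 953 and 950 CPM in midline libraries 2, 3 and 5. Egfl7 (-1.78, SE 0.35) kept its call with each library left out, while Cdh5 (-1.54, SE 0.45), a cadherin of endothelial cells, lost it without mechanoreceptor 8, mechanoreceptor 9, midline 2 or midline 5 (adjusted p = 0.0503 to 0.0996). Emcn (-1.10, SE 0.54, adjusted p = 0.1395) did not pass. Vtn (-2.33, SE 1.03, adjusted p = 0.108) passed without mechanoreceptor 2 (adjusted p = 0.0122), with DESeq2 (0.028) and with limma-voom (0.0489). Of 19 meningeal and connective tissue genes, 14 were higher in the midline and 0 in mechanoreceptors (15 and 0 adjusted over the list alone). The meningeal and connective tissue list had camera adjusted p = 2.16e-05, and adjusted p = 0.337 with an estimated correlation. The collagen genes Col3a1 (1094 ± 1337 against 45.8 ± 28.1 CPM, log2 fold change -4.58, SE 0.99, adjusted p = 0.00943) and Col1a1 (-5.002, SE 0.96) were highest in midline library 2, where the list summed to 9326 CPM against 1736 and 2760 CPM in libraries 3 and 5. The count was 7 without mechanoreceptor library 8 or 9. Col1a2 (-3.85, SE 0.86) lost its call without mechanoreceptor 9 (adjusted p = 0.0507). Without midline 2 the log2 fold changes of Col3a1, Col1a1 and Col1a2 were -2.79, -3.22 and -2.13. Postn (-1.57, SE 0.78, adjusted p = 0.148, or -0.0512 without midline 2) passed only without midline 3 (adjusted p = 0.0144). Dcn (-3.01, SE 1.05, adjusted p = 0.052995, or -1.10 without midline 2) passed without midline 3 (adjusted p = 0.0186), with upper-quartile scaling (0.0439), DESeq2 (0.0374) or no count filter (0.0396), and without muscle, keratinocyte and cartilage genes (0.0491).

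Adult haemoglobin genes were higher in the midline. Hba-a1 and Hba-a2, whose 6 counts were equal, stood at 157 ± 38.2 against 36.7 ± 14.996 CPM (log2 fold change -2.10, SE 0.33, adjusted p = 0.00262), and Hbb-b1 (now Hbb-bt) and Hbb-b2, also equal to each other, at 135 ± 31.9 against 22.4 ± 5.63 CPM (log2 fold change -2.59, SE 0.28, adjusted p = 0.000713). The embryonic gene Hbb-y went the other way (463 ± 124 against 155 ± 108 CPM, log2 fold change 1.58, SE 0.46, adjusted p = 0.0287), and lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 3 (adjusted p = 0.0515 to 0.0934). In the red blood cell list 7 of 10 genes were higher in the midline and 1 in mechanoreceptors (7 and 2 adjusted over the list alone). The red blood cell list had camera adjusted p = 0.00324, and adjusted p = 0.337 with an estimated correlation. The 2 pairs with equal counts make 4 of these 7, so 5 of the 7 are distinct measurements. Without the haemoglobin genes 3 members were higher in the midline and 0 in mechanoreceptors. The mechanoreceptor count was 0 in the fits in which Hbb-y lost its call and 2 without midline library 5 or with DESeq2. Hba-x (1.21, SE 0.47, adjusted p = 0.0761) passed without midline 5 (adjusted p = 0.015002) and with DESeq2 (0.0405), and Hbb-bh1 (0.78, SE 0.68, adjusted p = 0.395) did not pass. Of 16 microglia and macrophage genes, 2 were higher in the midline, Itgam (log2 fold change -2.93, SE 0.59, adjusted p = 0.00711) and Ptprc (log2 fold change -1.25, SE 0.40, adjusted p = 0.0389), and 0 in mechanoreceptors (1 and 0 adjusted over the list alone). The microglia and macrophage list had camera adjusted p = 0.309, and adjusted p = 0.812 with an estimated correlation. Ptprc lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9, midline 2 or midline 3 (adjusted p = 0.0603 to 0.125), with no count filter (0.0667) and on the deposited log2 values (0.186). The midline count was 1 in the last 2 of these and without mechanoreceptor library 8 or 9 or midline library 3. Csf1r (-0.81, SE 0.57, adjusted p = 0.289) and C1qb (-0.09, SE 0.54, adjusted p = 0.909) did not pass.

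Of 12 genes of ependymal cilia, 3 were higher in each group (3 and 3 adjusted over the list alone). The ependymal cilia list had camera adjusted p = 0.836, and adjusted p = 0.928 with an estimated correlation. Rfx3 (539 ± 388 against 44.1 ± 16.4 CPM, log2 fold change -3.61, SE 0.54, adjusted p = 0.00237) and Rfx2 (-3.001, SE 0.67), transcription factors of ciliated cells, and Hydin (-2.95, SE 0.55), a component of motile cilia, were higher in the midline. Tppp3 (358 ± 32.5 against 34.96 ± 16.4 CPM, log2 fold change 3.35, SE 0.38, adjusted p = 0.000908), Ccdc40 (2.13, SE 0.41) and Rsph1 (1.72, SE 0.50) were higher in mechanoreceptors, and Rsph1 lost its call without mechanoreceptor 8, mechanoreceptor 9 or midline 5 (adjusted p = 0.0509 to 0.102). Ccdc39 (-0.22, SE 0.20, adjusted p = 0.4096) and Spag6, now Spag6l (-0.56, SE 0.62, adjusted p = 0.503) did not pass.

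Transcripts of tissues outside the nervous system were counted in lists written after the largest changes had been seen, so these counts are no independent evidence of a direction. Of 38 skeletal muscle genes tested, 33 were higher in the midline and 0 in mechanoreceptors (37 and 0 adjusted over the list alone), and limma-voom called 6. The list took 5.32% of the counts of midline library 2 (95% interval 5.30 to 5.34), 0.526% of library 5 (0.520 to 0.532) and 0.0672% of library 3 (0.0647 to 0.0698), against 0.00871% to 0.0116% in mechanoreceptor libraries. Without midline library 2 the count was 32. Of 15 keratinocyte genes, 8 were higher in the midline and 0 in mechanoreceptors (8 and 0 adjusted over the list alone), with 0.132% of counts in midline library 2 (0.129 to 0.135) and 0.00994% and 0.0106% in libraries 3 and 5. That count was 3 without midline library 2, 13 without midline library 3, and 1, 4 and 3 without mechanoreceptor libraries 2, 8 and 9. Without midline library 2, 2 keratinocyte genes were higher in mechanoreceptors. With limma-voom the midline count was 1, and it was 3 on the deposited log2 values. Of 16 cartilage and bone genes, 14 were higher in the midline and 0 in mechanoreceptors (14 and 0 adjusted over the list alone), or 9 in the midline without midline library 2 or mechanoreceptor library 8 and 8 on the deposited log2 values.

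**Figure D3:**
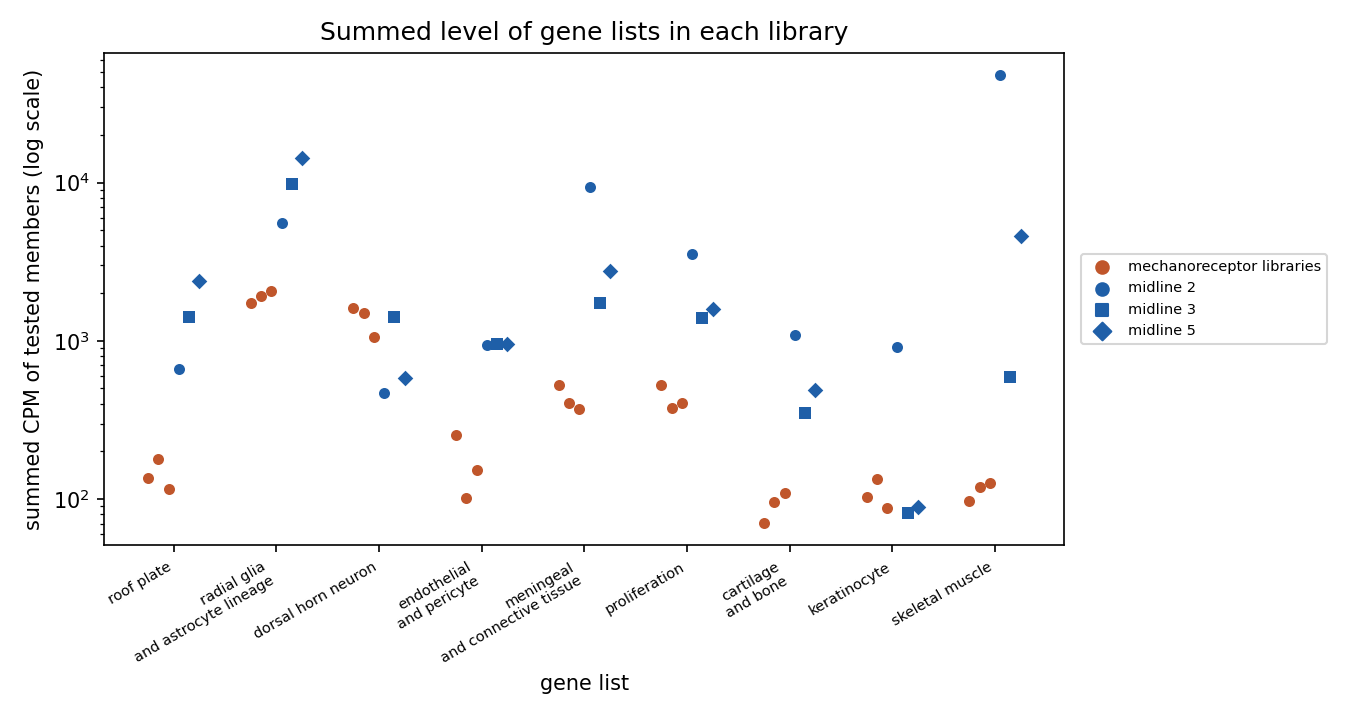
Summed CPM of the tested members of 9 gene lists on a log axis in each library, with orange points for mechanoreceptor libraries and blue points for midline libraries 2, 3 and 5 (circle, square, diamond). Skeletal muscle genes sum to 47626, 588 and 4630 CPM in midline libraries 2, 3 and 5, while roof plate genes sum to 662, 1423 and 2399 CPM.

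Axon guidance ligands went both ways. Of 34 tested, 12 were higher in the midline and 7 in mechanoreceptors (13 and 8 adjusted over the list alone). The axon guidance ligand list had camera adjusted p = 0.0541, and adjusted p = 0.449 with an estimated correlation. The ephrin gene Efnb3 (781 ± 727 against 7.96 ± 3.898 CPM, log2 fold change -6.61, SE 0.79, adjusted p = 0.00106), the repellent ligand gene Slit2 (522 ± 469 against 66.6 ± 27.7 CPM, log2 fold change -2.97, SE 0.63, adjusted p = 0.00882) and the semaphorin genes Sema6d (-2.01, SE 0.40) and Sema3c (-4.24, SE 0.52) were higher in the midline, each highest in library 5, as for Efnb3 at 319.7, 403 and 1619 CPM in libraries 2, 3 and 5. Without midline 5 the log2 fold change of Slit2 was -1.88. The ephrin gene Efna5 (305 ± 51.1 against 61.3 ± 21.2 CPM, log2 fold change 2.32, SE 0.30, adjusted p = 0.00144) and Sema4d (2.52, SE 0.25) were higher in mechanoreceptors. The midline count was 7 without mechanoreceptor library 9. Efnb2 (0.38, SE 0.34, adjusted p = 0.4105, or 0.18 without midline 2 and 0.20 without midline 3) passed only without midline 5 (adjusted p = 0.0217), and Sema6a (-0.20, SE 0.22, adjusted p = 0.487) did not pass.

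Of 33 axon guidance receptors, 15 were higher in the midline and 4 in mechanoreceptors (16 and 4 adjusted over the list alone). The axon guidance receptor list had camera adjusted p = 0.005095, and adjusted p = 0.334 with an estimated correlation. The 4 were the plexin genes Plxna4 (1057 ± 189 against 221 ± 108 CPM, log2 fold change 2.26, SE 0.38, adjusted p = 0.00345) and Plxna3 (1.56, SE 0.22), the semaphorin receptor gene Nrp1 (528 ± 121 against 146 ± 35.7 CPM, log2 fold change 1.85, SE 0.28, adjusted p = 0.00224) and the netrin receptor gene Unc5b (1.34, SE 0.25). The Wnt receptor gene Fzd3 (-2.16, SE 0.41), Plxnb2 (-1.49, SE 0.29) and the Slit receptor gene Robo2 (113 ± 41.95 against 36.3 ± 4.68 CPM, log2 fold change -1.64, SE 0.29, adjusted p = 0.00402) were higher in the midline. Plxna1 (log2 fold change -0.65, SE 0.21, adjusted p = 0.0405) lost its call in each of the 6 fits that left out a library (adjusted p = 0.0519 to 0.128) and with no count filter (0.0931). The netrin receptor gene Neo1 did not pass (log2 fold change 0.37, SE 0.34, adjusted p = 0.416), nor did Plxna2 (-0.55, SE 0.33, adjusted p = 0.221).

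Growth factor ligands showed no shift as a list, with 7 of 23 higher in the midline and 4 in mechanoreceptors (7 and 4 adjusted over the list alone). The neurotrophic factor and growth factor ligand list had camera adjusted p = 0.856, and adjusted p = 0.921 with an estimated correlation. The 4 were the neuregulin genes Nrg1 (229 ± 33.9 against 10.2 ± 3.25 CPM, log2 fold change 4.49, SE 0.30, adjusted p = 0.000178) and Nrg3 (2.61, SE 0.44), Bdnf (25.5 ± 5.401 against 2.5004 ± 1.99 CPM, 3.38, SE 0.64) and Fgf1 (77.9 ± 0.867 against 6.83 ± 5.92 CPM, 3.49, SE 0.53). Mdk, which encodes midkine, was higher in the midline (168 ± 107 against 13.5 ± 3.75 CPM, log2 fold change -3.63, SE 0.50, adjusted p = 0.00168), as was Igf2 (log2 fold change -3.17, SE 0.85, adjusted p = 0.0208), at 5516, 567 and 1079 CPM in libraries 2, 3 and 5. Igf2 lost its call without mechanoreceptor 8 or mechanoreceptor 9 (adjusted p = 0.0801 to 0.0804), and the midline count was then 4. Its log2 fold change was -1.61 without midline 2. Pros1 (-2.69, SE 0.35) kept its call with each library left out. Tgfa (-1.69, SE 0.53, or -1.07 without midline 3) lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9, midline 3 or midline 5 (adjusted p = 0.0506 to 0.109) and on the deposited log2 values (0.0919). Ptn (-0.46, SE 0.26, adjusted p = 0.203, or -0.27 without midline 5) passed without midline 2 (adjusted p = 0.0275) and on the deposited log2 values (0.0307), and Igf1 (-0.39, SE 0.61, adjusted p = 0.6405) did not pass.

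Of 36 neural adhesion genes, 11 were higher in mechanoreceptors and 4 in the midline (11 and 4 adjusted over the list alone). The neural adhesion molecule list had camera adjusted p = 0.0588, and adjusted p = 0.449 with an estimated correlation. L1cam (1049 ± 162 against 141 ± 85.5 CPM, log2 fold change 2.90, SE 0.42, adjusted p = 0.00208) and Alcam (947 ± 103 against 121 ± 26.95 CPM, log2 fold change 2.97, SE 0.25, adjusted p = 0.0003301), both immunoglobulin-type adhesion molecules of axons, were among the 11. Cntn1 (1.70, SE 0.28) was another, and Nrcam (1.30, SE 0.38) lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 5 (adjusted p = 0.05601 to 0.0874), with upper-quartile scaling (0.0537) and on the deposited log2 values (0.0509). Ncam1 did not pass (-0.08, SE 0.30, adjusted p = 0.855), and Cadm3 (0.65, SE 0.44, adjusted p = 0.267, or 0.30 without midline 2) passed only without midline 5 (adjusted p = 0.0444). The cadherin genes Cdh13 (-3.75, SE 0.49) and Cdh4 (-2.24, SE 0.30), Dscaml1 (-6.16, SE 0.72) and Cntn3 (-1.55, SE 0.45) were the 4, and Cntn3 lost its call without mechanoreceptor 2, mechanoreceptor 9 or midline 3 (adjusted p = 0.0832 to 0.0942) and on the deposited log2 values (0.108). Extracellular matrix genes were higher in the midline for 22 of 34 members and in mechanoreceptors for 1, Gpc1 (1.31, SE 0.28; 23 and 2 adjusted over the list alone). The extracellular matrix list had camera adjusted p = 1.02e-08, and adjusted p = 0.112 with an estimated correlation. The count toward mechanoreceptors was 3 without midline library 3, and 2 without midline library 5, with DESeq2 or with limma-voom. Sparc (1345 ± 351 against 209 ± 11.4 CPM, log2 fold change -2.69, SE 0.26, adjusted p = 0.000503) and the basement membrane gene Nid1 (890.5 ± 237 against 92.4 ± 8.39 CPM, log2 fold change -3.27, SE 0.27, adjusted p = 0.000314) were higher in the midline. Fibronectin, encoded by Fn1 (log2 fold change -3.29, SE 0.77, adjusted p = 0.0126), lost its call without mechanoreceptor 9 (adjusted p = 0.05496). Ptprz1 (-1.75, SE 0.39, adjusted p = 0.0107) kept its call with each library left out. Agrn (0.64, SE 0.23, adjusted p = 0.0621) passed without midline 5 (adjusted p = 0.0465), with DESeq2 (0.0436) and with limma-voom (0.0396), and Ncan (0.74, SE 0.48, adjusted p = 0.257, or 0.42 without midline 2) only without midline 3 (adjusted p = 0.00317).

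Most genes of the synaptic vesicle, ion channel and axonal cytoskeleton lists were higher in mechanoreceptors. Of 25 synaptic vesicle genes, 20 were higher there and 0 in the midline (22 and 0 adjusted over the list alone), among them Snap25, a subunit of the vesicle fusion complex (1729 ± 73.7 against 254 ± 209.7 CPM, log2 fold change 2.77, SE 0.55, adjusted p = 0.00673). The synaptic vesicle and release list had camera adjusted p = 2.85e-11, and adjusted p = 0.256 with an estimated correlation. Among midline libraries the list was highest in library 3, at 1218, 3926 and 1726 CPM in libraries 2, 3 and 5. Syt11 (1.75, SE 0.39) and Vamp2 (1.80, SE 0.30) were higher in mechanoreceptors too. Pclo (1.02, SE 0.37, adjusted p = 0.0626) passed without midline 3 (adjusted p = 0.00262), with DESeq2 (0.0325), limma-voom (0.0288) or no count filter (0.0394). Rab3c (0.43, SE 0.55, adjusted p = 0.568, or 0.0648 without midline 2 and 0.18 without midline 5) passed only without midline 3 (adjusted p = 0.00254). Of 33 ion channel genes, 20 were higher in mechanoreceptors and 2 in the midline (21 and 3 adjusted over the list alone). The neuronal ion channel list had camera adjusted p = 8.54e-12, and adjusted p = 0.137 with an estimated correlation. The sodium channel gene Scn9a (916 ± 234 against 19.7 ± 7.16 CPM, log2 fold change 5.54, SE 0.39, adjusted p = 0.000192) and the potassium channel gene Kcna1 (356 ± 59.5 against 6.65 ± 1.53 CPM, log2 fold change 5.74, SE 0.28, adjusted p = 6.43e-05) were among the 20, and the calcium channel genes Cacna1g (log2 fold change -4.99, SE 0.47, adjusted p = 0.000463) and Cacna1e (log2 fold change -1.30, SE 0.37, adjusted p = 0.0272) were the 2. Cacna1e, at -0.78 without midline 3, lost its call without mechanoreceptor 2, mechanoreceptor 8 or mechanoreceptor 9 (adjusted p = 0.05299 to 0.10004), and the midline count was then 1. Scn3b (1.51, SE 0.36) and Kcna2 (3.88, SE 0.49) were higher in mechanoreceptors. Cacna2d1 (1.21, SE 0.51, adjusted p = 0.0956) passed without midline 2 (adjusted p = 0.00184) and with limma-voom (0.0391), and Scn3a (0.33, SE 0.35, adjusted p = 0.491) did not pass. Of 24 axonal cytoskeleton genes, 20 were higher in mechanoreceptors and 0 in the midline (22 and 0 adjusted over the list alone), including the spectrin gene Spnb2, now Sptbn1 (3691 ± 466 against 957 ± 63.7 CPM, log2 fold change 1.95, SE 0.25, adjusted p = 0.00128). The axonal cytoskeleton list had camera adjusted p = 4.44e-16, and adjusted p = 0.137 with an estimated correlation. Dcx, doublecortin, did not pass (log2 fold change 1.10, SE 0.55, adjusted p = 0.151), at 623, 2668 and 738 CPM in midline libraries 2, 3 and 5, except without midline 3 (adjusted p = 0.00111). Kif1a did not pass either (log2 fold change 1.20, SE 0.45, adjusted p = 0.0675) except without midline 2 or midline 3 (adjusted p = 0.0199 to 0.0258), with DESeq2 (0.0252), with limma-voom (0.0348) and with no count filter (0.0431).

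Proliferation genes were higher in the midline for 29 of 30 members and in mechanoreceptors for 0 (30 and 0 adjusted over the list alone). The proliferation list had camera adjusted p = 8.54e-12, and adjusted p = 0.334 with an estimated correlation. Mki67, a marker of cycling cells, stood at 465 ± 338 against 74.8 ± 19.9 CPM (log2 fold change -2.64, SE 0.50, adjusted p = 0.00551) and the cyclin gene Ccnd2 at 188 ± 14.2 against 12.4 ± 4.71 CPM (log2 fold change -3.91, SE 0.30, adjusted p = 0.0002403). The list was highest in midline library 2, at 3534, 1387 and 1597 CPM in libraries 2, 3 and 5, and 24 members were higher in the midline without library 2. Top2a (-2.71, SE 0.54) kept its call with each library left out, and Ccna2 (-1.28, SE 0.41, or -0.59 without midline 2) lost it without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 2 (adjusted p = 0.0673 to 0.122). Aurka did not pass (log2 fold change -1.64, SE 0.62, adjusted p = 0.0676, or -0.88 without midline 2) except without midline 3 (adjusted p = 0.02396), with upper-quartile scaling (0.045) and with DESeq2 (0.0221).

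Of 19 Notch and Hes genes, 10 were higher in the midline and 2 in mechanoreceptors (12 and 2 adjusted over the list alone). The Notch and Hes signalling list had camera adjusted p = 0.00258, and adjusted p = 0.112 with an estimated correlation. The receptor genes Notch1 (-1.64, SE 0.37), Notch2 (180.5 ± 67.1 against 26.03 ± 6.84 CPM, log2 fold change -2.79, SE 0.35, adjusted p = 0.00124) and Notch3 (-2.95, SE 0.41) were among the 10, and the effector gene Hey1 (1.27, SE 0.29) and the ligand gene Jag2 (1.70, SE 0.41) were the 2. Jag2 lost its call without mechanoreceptor 2 (adjusted p = 0.0575). The mechanoreceptor count was then 1. Dtx4 (-1.20, SE 0.34, or -0.72 without midline 5), higher in the midline, lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 5 (adjusted p = 0.0794 to 0.0907). Rbpj (-0.25, SE 0.27, adjusted p = 0.503) and Hes6 (-0.43, SE 0.26, adjusted p = 0.222) did not pass. The midline count was 6 without any single mechanoreceptor library, 5 without midline library 5 and 5 on the deposited log2 values. In the Wnt and BMP pathway list 18 of 32 genes were higher in the midline and 1 in mechanoreceptors (19 and 1 adjusted over the list alone), or 2 in mechanoreceptors without midline library 2. The Wnt and BMP pathway list had camera adjusted p = 1.95e-06, and adjusted p = 0.0733 with an estimated correlation. Axin2, a target gene of Wnt signalling (77.8 ± 35.8 against 9.07 ± 1.61 CPM, log2 fold change -3.10, SE 0.37, adjusted p = 0.00106), Dkk3 (-4.40, SE 0.63) and Fzd1 (-2.89, SE 0.57) were higher in the midline, and Smad9 (34.6 ± 6.44 against 7.46 ± 2.07 CPM, log2 fold change 2.22, SE 0.31, adjusted p = 0.00175) in mechanoreceptors. Bmpr1a (log2 fold change -0.87, SE 0.24, adjusted p = 0.0218) lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 5 (adjusted p = 0.0605 to 0.0815). Lrp6 (-0.59, SE 0.27, adjusted p = 0.117, or -0.37 without midline 2 and -0.38 without mechanoreceptor 9) passed without midline 3 (adjusted p = 0.0373), with upper-quartile scaling (0.0447) and on the deposited log2 values (0.0306).

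Of 29 dissociation and immediate early genes, 13 were higher in mechanoreceptors and 2 in the midline (14 and 2 adjusted over the list alone). The dissociation and immediate early list had camera adjusted p = 0.00375, and adjusted p = 0.421 with an estimated correlation. Fos stood at 36.2 ± 13.9 against 1.69 ± 1.096 CPM (log2 fold change 4.36, SE 0.56, adjusted p = 0.00134), Jun at 125 ± 12.02 against 50.8 ± 14.4 CPM (log2 fold change 1.30, SE 0.24, adjusted p = 0.004901) and the chaperone gene Hsp90aa1 at 1035 ± 157 against 339 ± 45.6 CPM (log2 fold change 1.61, SE 0.23, adjusted p = 0.00179). The mechanoreceptor libraries were the dissociated and sorted ones. Klf6 (1.55, SE 0.24) was higher there, and Myc (1.26, SE 0.34) lost its call without mechanoreceptor 8 or mechanoreceptor 9 (adjusted p = 0.0613 to 0.0685). Rhob (0.50, SE 0.23, adjusted p = 0.125) passed only without midline 3 (adjusted p = 0.0211), and Dnajb1 (0.45, SE 0.18, adjusted p = 0.0793) only without midline 3 (adjusted p = 0.0411). Klf4 (-2.80, SE 0.41) and Klf2 (-1.85, SE 0.59) were higher in the midline, and Klf2 lost its call without mechanoreceptor 9, midline 2, midline 3 or midline 5 (adjusted p = 0.0527 to 0.0976) and on the deposited log2 values (0.056). The midline count was 1 without mechanoreceptor library 9, midline library 2 or midline library 5, and on the deposited log2 values. The mechanoreceptor count was 7 without mechanoreceptor library 2, 6 without mechanoreceptor library 9, 8 without midline library 5 and 8 on the rows the authors marked as best.

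Of 29 Hox genes, which mark position along the body axis, 17 were higher in the midline and 2 in mechanoreceptors (19 and 2 adjusted over the list alone). The Hox cluster gene list had camera adjusted p = 0.00561, and adjusted p = 0.449 with an estimated correlation. Hoxb3 stood at 96.9 ± 23.9 against 27.5 ± 5.75 CPM (log2 fold change -1.81, SE 0.27, adjusted p = 0.00212). Hoxb9 was lower in midline library 2 than in libraries 3 and 5 (22.8, 209 and 241 CPM, log2 fold change -3.16, SE 0.73, adjusted p = 0.0118), and lost its call without mechanoreceptor 2 or mechanoreceptor 9 (adjusted p = 0.0516 to 0.0546) and with limma-voom (0.0565). Hoxb7 (-1.47, SE 0.48, or -0.83 without midline 5) lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9, midline 3 or midline 5 (adjusted p = 0.0567 to 0.16002), with limma-voom (0.0883) and on the deposited log2 values (0.0747). Hoxc8 (-2.40, SE 0.62) lost it without mechanoreceptor 2, mechanoreceptor 9 or midline 5 (adjusted p = 0.0559 to 0.0768) and with limma-voom (0.0551). Hoxb6 (-1.02, SE 0.39, adjusted p = 0.0731) passed without midline 2 (adjusted p = 0.00566), with upper-quartile scaling (0.0381) and with DESeq2 (0.0349). Hoxa5 (-1.04, SE 0.38, adjusted p = 0.0619, or -0.55 without midline 5) passed without midline 2 (adjusted p = 0.0178), with upper-quartile scaling (0.0308), with DESeq2 (0.0274) and with the stricter filter (0.0456). Hoxd1 (28.2 ± 0.885 against 0.928 ± 1.14 CPM, log2 fold change 4.84, SE 0.69, adjusted p = 0.00187) and Hoxd10 (4.33 ± 2.38 against 0.0535 ± 0.0926 CPM, 73.9-fold, 95% interval 13.3 to 2919) were higher in mechanoreceptors. Hoxd10 was at least 15.96-fold higher without midline 2 and 47.8-fold without midline 5, and the filter removed it without mechanoreceptor 2 or 9. The midline count was 7, 11 and 7 without mechanoreceptor libraries 2, 8 and 9 and 8 without midline library 5. The mechanoreceptor count was 1 without mechanoreceptor library 2 or 9 or with the stricter filter, and 4 without midline library 3.

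Of 12 long noncoding RNA genes, 3 were higher in each group (3 in mechanoreceptors and 4 in the midline adjusted over the list alone). The nuclear-retained and long noncoding RNA list had camera adjusted p = 0.927, and adjusted p = 0.967 with an estimated correlation. The median log2 fold change was -0.39 and the mean -0.23, while the direction of the test was toward mechanoreceptors. Snhg11 (3772 ± 525 against 339 ± 216 CPM, log2 fold change 3.48, SE 0.55, adjusted p = 0.00277), Miat (2.35, SE 0.30) and Meg3 (log2 fold change 1.37, SE 0.46, adjusted p = 0.0472) were higher in mechanoreceptors, and H19 (log2 fold change -2.95, SE 0.92, adjusted p = 0.0357), Kcnq1ot1 (-2.42, SE 0.42) and 2610307P16Rik (-2.32, SE 0.46) in the midline. H19, at 2805, 147 and 533 CPM in midline libraries 2, 3 and 5 and a log2 fold change of -1.15 without midline 2, lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9 or midline 2 (adjusted p = 0.0837 to 0.118), with limma-voom (0.0919) and on the deposited log2 values (0.0702). Meg3, at 2.06 without midline 2, lost its call without mechanoreceptor 2, mechanoreceptor 8, mechanoreceptor 9, midline 3 or midline 5 (adjusted p = 0.0844 to 0.114), with relative log expression scaling (0.053), with upper-quartile scaling (0.085), with the stricter filter (0.061) and on the deposited log2 values (0.092). Malat1, a nuclear RNA, did not differ beyond the spread (16480 ± 3120 against 13712 ± 2398 CPM, log2 fold change 0.27, SE 0.34, adjusted p = 0.565). Rian (0.52, SE 0.57, adjusted p = 0.501, or 0.14 without midline 3 and 0.26 without midline 5) passed only without midline 2 (adjusted p = 0.00126).

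Across the 26 fixed lists, 20 passed the camera test with the preset correlation, 7 toward mechanoreceptors and 13 toward the midline. With an estimated correlation 0 lists passed, with a lowest adjusted p of 0.0633, while fry, which does not compare a list with other genes, gave 21 lists for a shift in a direction and 25 for a change in either.

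In the authors' deposited table, 2952 gene symbols were marked higher in the midline and 3085 higher in mechanoreceptors, and 2 symbols stood in both. Of these, 2156 and 2638 were also called in the same direction by the test used here, and 1 was called in the opposite direction. In the authors' deposited table of pathways for the genes higher in the midline, 18 of 36 pathways had a Benjamini-adjusted p under 0.05. ECM-receptor interaction had the lowest adjusted p in that deposited table by the authors (8.2e-12), with 36 genes and a fold enrichment of 4.13. Other pathways in the authors' deposited table had more genes or a higher fold. The authors' deposited table also gave folds of 2.24 for Wnt signaling (adjusted p = 0.000139), 2.69 for dilated cardiomyopathy (adjusted p = 0.000101), a pathway of cardiac muscle genes, and 1.67 for axon guidance (adjusted p = 0.119). These lists were chosen on the same samples and are no independent evidence.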

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

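The rows marked best by the authors, all transcript rows, the deposited log2 values and the omission of muscle, keratinocyte and cartilage genes were chosen as tests after the results were seen. The count of 5788 differing genes stayed within 1.5 times its size under relative log expression (5752), upper-quartile scaling (5822), DESeq2 (6578), limma-voom (5975), no count filter (5878), the stricter filter (5151), omission of haemoglobin genes (5784), rows marked best (5602), all transcript rows (5824), the deposited log2 values with limma (5174) and omission of the muscle, keratinocyte and cartilage genes (5763). It was 2232 against a 2-fold change (954 higher in mechanoreceptors, 1278 in the midline) and 2854 at an adjusted p under 0.01 (1544 and 1310); both are narrower by construction. With 1 library left out the count ranged from 3755 to 6181, from 1893 to 3099 in mechanoreceptors and from 1862 to 3082 in the midline; fewer samples enter these fits, and the lowest values were without mechanoreceptor 8. Upper-quartile scaling moved the median log2 fold change of all genes from -0.05 to -0.26, and 36.9% of its calls were higher in mechanoreceptors against 49.9%. Lists past the camera test numbered 20 to 21 with 1 library left out, and 0 with an estimated correlation, where the preset correlation gave 20, fry 21 and 25, and both relative log expression and lists without shared genes 20.

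Of 159 called genes named, 123 kept their call at an adjusted p under 0.05 in each fit with another scaling, test, filter, row choice, gene omission or left-out library in which they were tested, and 36 lost it in at least 1 of these. The 2 stricter thresholds were set for the total counts and not applied to single genes or list members; 1 called gene reversed. That gene was Mbp, at -0.95 on rows marked best, which is another transcript. A further 7 genes, not called, reversed. The cause was not tested. Their values follow with the far end, or the whole, of the range over left-out libraries. Ednrb was 0.19 without midline 5 and -0.82 without mechanoreceptor 8. Mog was 0.20 without midline 3, -0.97 without midline 5 and 0.41 on the deposited log2 values. C1qb was 8.6e-05 with no filter, 0.30 without mechanoreceptor 8, 0.48 without midline 5 and -0.41 without midline 2. On the deposited log2 values Spag6 was 0.32 and Neo1 -0.0155. Over left-out libraries Spag6 ran from -0.96 to -0.064 and Neo1 from 0.20 to 0.85. Igf1 was 0.0615 with limma-voom, 0.78 without midline 2 and -0.82 without midline 3. Ncam1 was 0.0125 with no filter, 0.07 without mechanoreceptor 9 and 0.16 without midline 3. It was 0.0045 without midline 5 and -0.30 without midline 2. Of the counts of list members, 840 stayed within 1.5 times and 82 did not. No paired analysis was made, since the groups came from embryos of different genotype and the labels state no pairing of libraries. The 1 replicate number that both groups share is not stated to mark a pair. The 2 alternatives set for normalized values were not run, since counts were deposited. In the simulation, 2-fold changes were mostly missed (19 of 972 recovered). It changed far fewer genes than the 5788 called here, which makes an adjusted p harder to pass. That share therefore does not carry over to the real comparison. A gene that did not pass is still not shown to be equal.

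The 6 libraries make 10 splits into 3 and 3, so no share of splits can be under 0.1. The real split gave 5788 differing genes, 2886 higher in mechanoreceptors and 2902 in the midline, and the highest other split 0 in each; 1 of 10 splits was as large. For lists the real split gave 20 and the highest other 18, again 1 of 10. The other 9 splits gave 11 to 18 lists with 0 genes called. Each of them sets 2 libraries of 1 cell type and 1 of the other against the rest, so part of the real difference stays in the comparison. Each also mixes both cell types within a group, which widens the spread there. The 0 genes called in these splits are therefore no measure of chance. The cause of the list calls in these splits was not tested.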

Other observations

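The tests on skeletal muscle and on immediate early genes were chosen after the results they measure had been seen. Those on dorsal horn genes were set before theirs.

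Both sexes were represented in most libraries. Xist, the RNA of the inactive X chromosome of females, stood at 269, 551 and 1.79 CPM in mechanoreceptor libraries 2, 8 and 9 and at 6.42, 1088 and 1972 CPM in midline libraries 2, 3 and 5. The Y-linked gene Eif2s3y stood at 75.3, 35.4 and 101 CPM and at 121, 60.9 and 48.1 CPM in the same libraries. Mechanoreceptor library 9 and midline library 2 had the lowest Xist levels and the highest Eif2s3y levels of their groups. Haemoglobin genes took 0.0446% to 0.0823% of counts in mechanoreceptor libraries and 0.0628% to 0.109% in midline libraries. Hba-a1 and Hba-a2 had equal counts, as did Hbb-b1 and Hbb-b2, and every symbol was summed. The same counts thus enter these shares more than once, and weigh more in the midline, where these genes were higher. The shares of the groups are therefore not comparable.

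Skeletal muscle genes stood apart in midline library 2, where they took 5.32% of counts, with Myh3 at 4302 CPM and Actc1 at 2984 CPM. A candidate explanation is that muscle beside the cord was captured or carried over with the midline cells, which no sort or gate would have removed. Of 26 tested muscle genes whose values had not been seen when the list was written, 26 (100%) were highest in midline library 2. The muscle list shares 0 members with the fixed lists. Muscle genes can move together whatever their source, so the 26 of 26 cannot tell captured muscle from another origin. The median log2 ratio of library 2 to library 5 was 3.25 (quartiles 2.93 to 3.44) for muscle and -1.77 (-2.42 to -0.37) for roof plate genes, a difference of 5.02. This argues only against muscle genes being expressed by the midline cells in a fixed proportion to their roof plate genes. The muscle list held members already seen high in library 2, so its ratio is no independent evidence, and other expression by the midline cells is not excluded. Whether muscle tissue entered at all, and if so at capture or later, stays open, and no other biological explanation was tested.

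Dorsal horn neuron genes were higher in midline library 3 than in library 5, with a median log2 ratio of 1.51 (quartiles 0.63 to 1.62). The lower depth of library 3 would move other genes of like expression alike. Among 10000 random lists matched on mean expression the medians ran from -0.80 to 0.74, and the dorsal horn list lay at percentile 100. This argues against depth alone as the cause. The list had been singled out for its height in library 3, so a high percentile was likely beforehand. A candidate explanation is that more dorsal horn neurons, or their processes, were captured in library 3. The 24 synaptic vesicle genes outside the list were higher there too, with a median of 1.09 (quartiles 0.69 to 1.60). Most genes of that list were higher still in mechanoreceptors, so they cannot single out dorsal horn neurons among neurons. Axonal cytoskeleton genes also summed higher in library 3 than in library 5 (11673 against 5670 CPM). Pan-sensory neuron genes summed to 1484 against 638 CPM, while their median was lower in library 3 (3.01 against 7.26 CPM). A difference in the position of the captured area along the cord stays open and was not tested.

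In the list of 29 dissociation and immediate early genes, 13 were higher in mechanoreceptors, 2 in the midline and 14 did not pass, with a median log2 fold change of 1.26. Not all 13 are immediate early genes, as the chaperone gene Hsp90aa1 was among them. The count of 13 was 7, 6 and 8 without mechanoreceptor 2, mechanoreceptor 9 or midline 5, and the list did not pass with an estimated correlation (adjusted p = 0.421). Enzymatic dissociation and sorting may have induced the 13, but every sorted library was a mechanoreceptor library, so this and a difference between the cell types cannot be told apart.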
